A study of Mus musculus with 2 samples.

How the data were processed

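The study immunoprecipitated chromatin with an antibody against Usp16, a deubiquitinase of histone H2A, from bone marrow cells of mice that were positive for c-Kit and Sca-1, the surface proteins used to enrich blood stem and progenitor cells. A second library was made with IgG from the same kind of cells. Chromatin was sheared by sonication to fragments of about 200 bp, per the labels' protocols. The mice carried the Mx1-Cre recombinase and loxP-flanked Usp16 alleles, per the labels' protocols, and the labels do not say whether the recombinase had been induced. It is therefore open whether the cells held Usp16, and a Usp16 ChIP peak here means a peak listed for the anti-Usp16 library. The design therefore holds 1 library per antibody and no replicates, so no test across samples was possible and every test below describes a single list of peaks.

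The data analysed here are 1 list of called peaks, each with a position, a name and a score. Per the file headers, the authors called the peaks with MACS run in Galaxy. The submitters' processing notes name Bowtie, Picard and the mouse genome build mm10, without versions. The MACS version, its settings and the use made of the IgG library in the peak call are not given in the sources used here. The deposited score is the peak caller's own value for each peak, and it was used only within this list, to rank, filter and describe peaks and to compare their medians. Its smallest value was 50, so weaker sites are not listed and the absence of a peak is not evidence of absent binding. Read depth is unknown, and the signal of the IgG library was not analysed here, so no background level stands beside the values.

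Peak starts were converted to 1-based positions and the midpoint was taken as a peak's position. The list has 1 peak whose start lies before the first base of its contig, and it was kept. Genes were taken from a RefSeq gene table of GRCm38.p6, the assembly that mm10 names, with 49943 gene records on the assembled nuclear chromosomes. This table gives both ends of each gene but no strand, and no genome sequence was used. The planned analyses at transcription start sites were for that reason run on both annotated ends of each gene, so start and end of transcription are not distinguished. The planned analyses of promoter CpG content, sequence motifs, exons, untranslated regions and the most upstream start were not run.

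A gene was said to carry a gene-end peak when a peak overlapped, by 1 bp or more, the window reaching 1 kb to either side of one of its ends. The share of peak midpoints within 1 kb of any annotated gene end was compared with 1000 random placements of the peaks on the same chromosomes, between the first and last annotated gene. This span stood in for the planned chromosome length, and assembly gaps and unmappable sequence inside it were not excluded. The planned classes were reduced to gene ends, gene interiors and the space between genes. The two-sided permutation p that 1000 placements can give is no smaller than 0.002. Peaks per chromosome were compared with the share of annotated length by a two-sided exact binomial test, with Benjamini-Hochberg adjustment over the 21 chromosomes. Scores and widths at gene ends and elsewhere were compared by a two-sided permutation test of the difference in medians with 100000 resamples.

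Before the data were examined, 26 gene lists were fixed, 16 by symbol and 10 by a symbol pattern. Each was compared with the other protein-coding genes on the same chromosomes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. Odds ratios are conditional maximum likelihood estimates with exact 95% intervals, and intervals of shares are exact Clopper-Pearson intervals. All intervals cover counting error only. Neighbouring genes can share a peak, so genes and peaks are not independent replicates, and every p-value and interval describes this 1 list.

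The genes named were chosen by a rule fixed at the same time. This rule read transcription start sites, which became gene ends here. It names the 10 protein-coding genes with the highest-scoring gene-end peak, up to 4 members of each list with the highest-scoring peaks and up to 2 members without one in alphabetical order, and Usp16, Cdkn1a, Cdkn2a, Kit and Ly6a. Some genes that this rule selects are not reported here. The 5 highest-scoring peaks farther than 10 kb from any annotated gene end were also named. The alternatives tried were the 2524 peaks with a score at or above the median, windows of 500 bp and 5 kb, any overlap in place of the midpoint, overlap by at least 50% of the peak, protein-coding genes only, the removal of chromosomes X and Y, merging of peaks within 1 kb, and the share of genes in place of length. Added after the data were seen were the comparison of widths, the counts at genes that are not protein-coding, random shifts of up to 1 Mb, strata of gene length and neighbouring gene ends, removal of peaks at tRNA, snRNA and snoRNA gene ends, counting genes that share a peak once, and the shares of classes among the peaks away from gene ends. The neighbouring gene ends in the strata were those of other protein-coding genes within 2 kb.

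The steps were tested on simulated data. Of 200 genes seeded with a peak among 21887 genes, 200 were recovered. The seeded peaks were placed inside the search window by design, so this recovery checks only that the steps ran correctly. Of 200 random lists of 80 genes, drawn against the real peaks, 9 had an unadjusted p under 0.05 in the list test. These lists held scattered genes, so they do not show how the list test behaves for clustered genes that share peaks. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and statsmodels 0.14.6 were used.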

Results

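The peak list from the Usp16 ChIP of c-Kit and Sca-1 positive bone marrow cells held 5079 peaks, which covered 3986 kb of the mm10 genome. Peaks were narrow, with a median width of 685 bp and quartiles of 560.5 and 911 bp. The peak caller's score had a median of 70.1, with quartiles of 57.9 and 97.5 and a maximum of 2409. On the assembled chromosomes there were 5046 peaks, and these entered every comparison with genes. The remaining 33 peaks lay on 9 contigs outside the assembled chromosomes. The list came from 1 immunoprecipitated library, with 1 IgG library beside it in the study and no replicates.

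The first question, from the study's stated aim of finding genes enriched for Usp16, was where the peaks lay relative to genes. The ends of protein-coding genes were the main location: 46.7% of peaks (2356 of 5046, 95% interval 45.3 to 48.1%) had their midpoint within 1 kb of one, against 3.15% ± 0.25 (SD over 1000 random placements). A further 6.38% lay within 1 kb of an end of another kind of gene, where random placement gave 3.26%. Peaks inside protein-coding genes but away from their ends made up 21.7%, where random placement gave 37.8%, and peaks inside other genes made up 4.22% against 6.94%. Peaks between genes made up 21.0% against 48.8%. Each of the 5 shares differed from random placement with a permutation p of 0.002, the smallest that 1000 placements can give, but the last 3 shares are lowered by the many peaks at gene ends. Among the 2368 peaks away from gene ends, a comparison chosen after seeing the data, 46.2% lay inside protein-coding genes against 40.1% of random positions away from ends (permutation p = 0.002) and 8.99% inside other genes against 7.41% (permutation p = 0.010). Between genes lay 44.8% against 52.5% (permutation p = 0.002). Random shifts of up to 1 Mb were not run for these shares, so the gene density around the peaks was not taken into account.

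Over all annotated genes, 53.1% of peaks (2678 of 5046, 95% interval 51.7 to 54.5%) lay within 1 kb of a gene end, which was 8.29 times the random share of 6.4% ± 0.35 (SD over placements, permutation p = 0.002). When each peak was instead shifted by up to 1 Mb, which keeps it near its own neighbourhood and was chosen after seeing the data, the random share was 9.30% and the ratio 5.71. The ratio fell to 2.78 for a window of 5 kb and stood at 13.9 for a window of 500 bp. The median distance from a peak to the nearest protein-coding gene end was 1692.5 bp, and 25.2% of peaks (1271) lay farther than 10 kb from any annotated gene end.

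**Figure D1:**
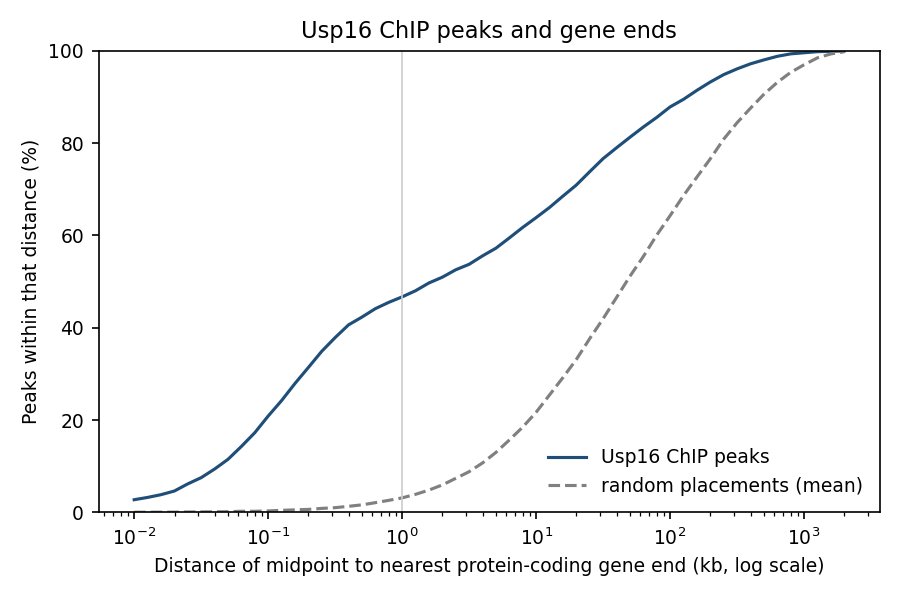
Cumulative share of the 5046 Usp16 ChIP peaks (solid line, percent) against the distance of their midpoint to the nearest protein-coding gene end (kb, log scale), with the mean of 20 random placements (dashed line). At 1 kb, marked by the thin vertical line, 46.7% of peaks had been reached, against about 3.15% of random positions.

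Peaks at gene ends scored higher and were wider than the rest. The median score was 75.4 for the 2678 peaks within 1 kb of a gene end (quartiles 59.7 and 106.5) and 65.4 for the other 2368 (quartiles 56.3 and 85.1), a difference of 9.97 (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give). The median width was 785.5 bp at gene ends and 597 bp elsewhere (difference 188.5 bp, same permutation p). The share of peaks at gene ends was 42.1% among the 506 lowest-scoring and 66.1% among the 505 highest-scoring peaks. It was 19.5% among the 513 narrowest and 79.6% among the 505 widest peaks. The comparison of widths was chosen after seeing the data.

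The autosomes carried between 1.57 and 2.79 peaks per Mb of annotated span, lowest on chromosome 12 and highest on chromosome 11. Chromosome X carried 0.53 per Mb (91 peaks, 95% Poisson interval 0.43 to 0.65) and chromosome Y 0.08 per Mb (7 peaks, 0.03 to 0.16). Against the share of length, the number on X was 0.29 times and on Y 0.04 times the expected one (exact binomial test, adjusted p = 2.8e-52 and 7.0e-62). Higher numbers than expected from length were found on chromosomes 2, 7, 9, 10, 11, 17 and 19, and chromosome 12 was lower (exact binomial test, adjusted p between 6.2e-12 and 0.029). Set against the share of protein-coding genes, X and Y remained low at 0.41 and 0.12 times the expected number, and chromosomes 1, 3, 10, 12, 13 and 18 were higher (exact binomial test, adjusted p between 1.0e-05 and 0.035). Chromosome 7, which holds 2030 protein-coding genes, changed from 1.30 to 0.76 times the expected number (exact binomial test, adjusted p = 6.9e-08), and chromosome 11 changed from 1.49 to 0.92 (adjusted exact p = 0.21). Chromosomes 9, 17 and 19 changed from above 1 to 0.98, 0.99 and 0.92 and no longer passed, chromosome 12 changed from 0.84 to 1.20, and chromosome 2 was at 1.02. With the 2524 highest-scoring peaks, chromosomes 9, 10 and 12 no longer passed the threshold against length.

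**Figure D2:**
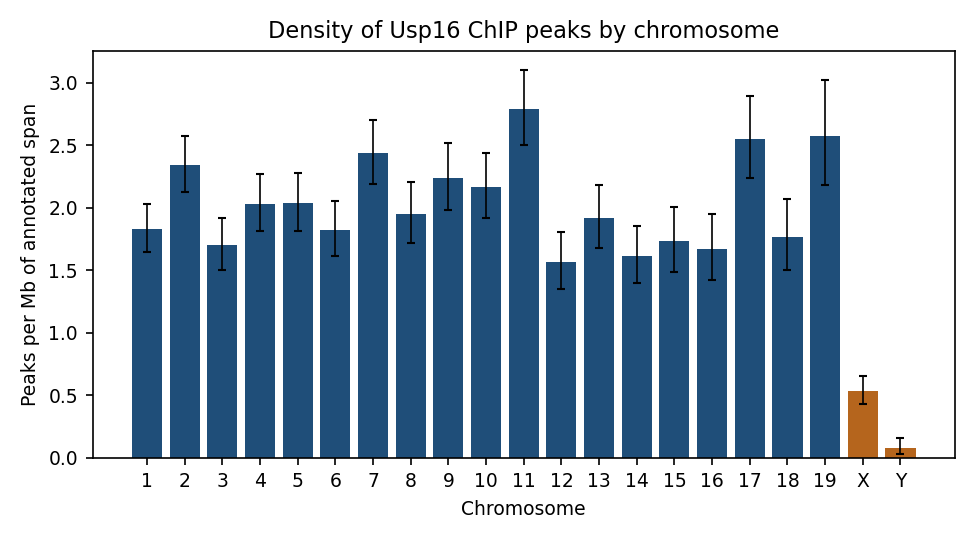
Usp16 ChIP peaks per Mb of annotated span (bars) on each chromosome, with 95% Poisson intervals for counting error (lines), autosomes in blue and sex chromosomes in brown. Autosomes range from 1.57 to 2.79 peaks per Mb, and chromosomes X and Y lie at 0.53 and 0.08.

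Of 21887 protein-coding genes, 3033 carried a gene-end peak (13.9%, 95% interval 13.4 to 14.3%). These genes were reached by 2461 peaks, of which 614 (24.9%) lay at ends of 2 or more genes. Such sharing is given below only for some of the named genes, so other named peaks may also lie at ends of further genes. Among genes longer than 10 kb, whose ends are well apart, 2101 carried a gene-end peak, and only 29 of them carried one at both ends. The peak lay at the end with the lower coordinate in 1051 and at the end with the higher coordinate in 1021 of these genes (two-sided exact binomial p = 0.52). Genes lie on both strands and strand was not used. This split therefore cannot show whether peaks prefer the start or the end of transcription.

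The highest-scoring gene-end peak of a protein-coding gene was at Vmn2r29, a gene of the vomeronasal receptor family, which has many similar copies (score 582, chromosome 7, 7277583 to 7278757, over the gene's upper end at 7278289). It was followed by Denr, which encodes a factor in translation re-initiation and ribosome recycling (score 505, chromosome 5, 123906767 to 123907490), and Rnf44, a RING finger gene (score 480.0, chromosome 13, 54693634 to 54694895). Next came Fosb, a subunit gene of the AP-1 transcription factor (score 447, chromosome 7, 19300630 to 19301759), whose peak also reached the end of the lncRNA gene Gm26802. This peak lay outside Fosb, with its midpoint 1.502 kb from the gene's end, and did not count for Fosb with a window of 500 bp or with overlap by at least 50% of the peak. Dynll1, a dynein light chain gene, had a peak of score 443 that it shared with the lncRNA gene Gm13830 (chromosome 5, 115299931 to 115301644), and the ubiquitin protease gene Usp31 had one of 437 (chromosome 7, 121707356 to 121707757). A single peak of score 408 lay where the ends of Atxn7l2 and Sypl2 meet (chromosome 3, 108209904 to 108210672). Another of score 402 covered an end of Med16, a Mediator subunit gene, and lay within 1 kb of an end of R3hdm4 (chromosome 10, 79908647 to 79909634), and this peak also reached the snRNA gene Gm24019. R3hdm4 had a different, lower-scoring peak with its midpoint 0.002 kb from one of its ends.

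No gene-end peak was listed for Usp16 itself (chromosome 16, 87454985 to 87483515), whose nearest peak midpoint lay 12.5 kb from an end of the gene. None was listed for Kit (chromosome 5, 75574987 to 75656722) and Ly6a (chromosome 15, 74994877 to 74998031), the genes of the 2 proteins used to select the cells, with the nearest midpoints 265 and 26.5 kb away. The cyclin-dependent kinase (CDK) inhibitor genes Cdkn1a (chromosome 17, 29090979 to 29100722) and Cdkn2a (chromosome 4, 89274473 to 89294619) had none either, with the nearest midpoints 168 and 57.3 kb away. None of these 5 genes held a peak inside it.

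Whether groups of genes with a shared function carried gene-end peaks more or less often than other protein-coding genes was tested on the 26 lists. Of these, 8 carried peaks more often, 2 less often, and 16 did not pass the threshold (Fisher's exact test, adjusted p under 0.05). Without adjustment, 12 passed.

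Genes for cytosolic and mitochondrial ribosomal proteins and for the proteasome, which degrades proteins, carried peaks more often than other genes. Of 84 ribosomal protein genes, 53 carried a gene-end peak (63.1%, odds ratio 10.8, 95% interval 6.79 to 17.4, adjusted exact p = 3.1e-24), through 57 distinct peaks. The highest scores were at Rpl22 (302), Rps7 (251), Rpl3 (196) and Rpl7l1 (188), a ribosomal protein-like gene, and Rpl10l and Rpl11 carried none. The Rpl22 peak lay inside the gene, with its midpoint 1.452 kb from the gene's end, and also reached the lncRNA gene 9430083M05Rik. It did not count for Rpl22 with a window of 500 bp or with overlap by at least 50% of the peak. The Rpl3 peak also reached the snoRNA gene Snord43. The odds ratio of this list was 6.47 without the peaks at tRNA, snRNA or snoRNA gene ends, a setting chosen after seeing the data, and 6.80 with the 2524 highest-scoring peaks. Of 78 mitochondrial ribosomal protein genes, 36 carried a peak (46.2%, odds ratio 5.38, interval 3.34 to 8.62, adjusted exact p = 2.9e-11). These were led by Mrpl44 (318), Mrpl21 (226), Mrpl3 (222) and Mrps27 (191), while Mrpl10 and Mrpl14 had none. The peaks at Mrpl44, Mrpl21 and Mrps27 also reached the protein-coding genes Wdfy1, Ighmbp2 and Ptcd2. Within strata of gene length and neighbouring gene ends, also chosen after seeing the data, the odds ratio was 3.54. Among 39 proteasome genes 14 carried a peak (35.9%, odds ratio 3.49, interval 1.68 to 6.99, adjusted exact p = 0.0015), led by Psmb5 (293), Psmb2 (192), Psmd1 (163) and Psmd3 (156), and Psma2 and Psma4 had none.

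Histone, splicing, respiratory chain and DNA repair genes also carried peaks more often. Of 63 replication-dependent histone genes, which lie in clusters, 37 carried a peak (58.7%, odds ratio 8.94, interval 5.26 to 15.4, adjusted exact p = 8.1e-16), but only 23 distinct peaks lay behind them. The highest scores were 103 at the peak shared by H2bc18 and H3c13 and 92.7 at the peak shared by H2ac6 and H2bc4, and H1f1 and H1f5 had none. The odds ratio of this list was 4.51 within the strata, 5.56 with genes that share a peak counted once, 4.99 with the 2524 highest-scoring peaks and 17.4 with a window of 5 kb. Near-identical histone gene copies make the assignment of reads to single copies uncertain. Of 77 splicing genes 32 carried a peak (41.6%, odds ratio 4.46, interval 2.74 to 7.18, adjusted exact p = 9.7e-09), led by Snrpa1 (154), Sf3a3 (138), Lsm6 (135) and Snrpd3 (132), while Hnrnpa0 and Hnrnpa1 had none. Of 81 oxidative phosphorylation genes 28 carried a peak (34.6%, odds ratio 3.31, interval 2.01 to 5.33, adjusted exact p = 7.5e-06). These were led by Ndufs7 (290), whose peak also covered the tRNA genes n-TFgaa3 and n-TNgtt7, and by Atp5pb (273), Uqcrh (221) and Ndufs1 (192). Atp5a1 and Atp5c1 had none.

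Of 30 DNA repair genes 11 carried a peak (36.7%, odds ratio 3.61, interval 1.55 to 7.99, adjusted exact p = 0.0044). The highest scores were at Prkdc (159), Ercc2 (144), Lig4 (119) and Xpc (113), while Atm and Brca1 had none. Of 367 genes named Zfp and a number, a name given to zinc finger proteins, 71 carried a peak (19.3%, odds ratio 1.5, interval 1.14 to 1.96, adjusted exact p = 0.0095). These were led by Zfp646 and Zfp668, which share a peak of score 239, and by Zfp672 (197) and Zfp524 (159), while Zfp1 and Zfp101 had none. With the 2524 highest-scoring peaks neither list passed, at odds ratios of 2.87 for DNA repair genes and 1.17 for the Zfp genes (adjusted exact p = 0.077 and 0.65). Under the other settings tried the adjusted p ranged from 0.0040 to 0.040 for DNA repair genes and from 0.0019 to 0.024 for the Zfp genes, with exact tests or, for strata, the Mantel-Haenszel test.

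**Figure D3:**
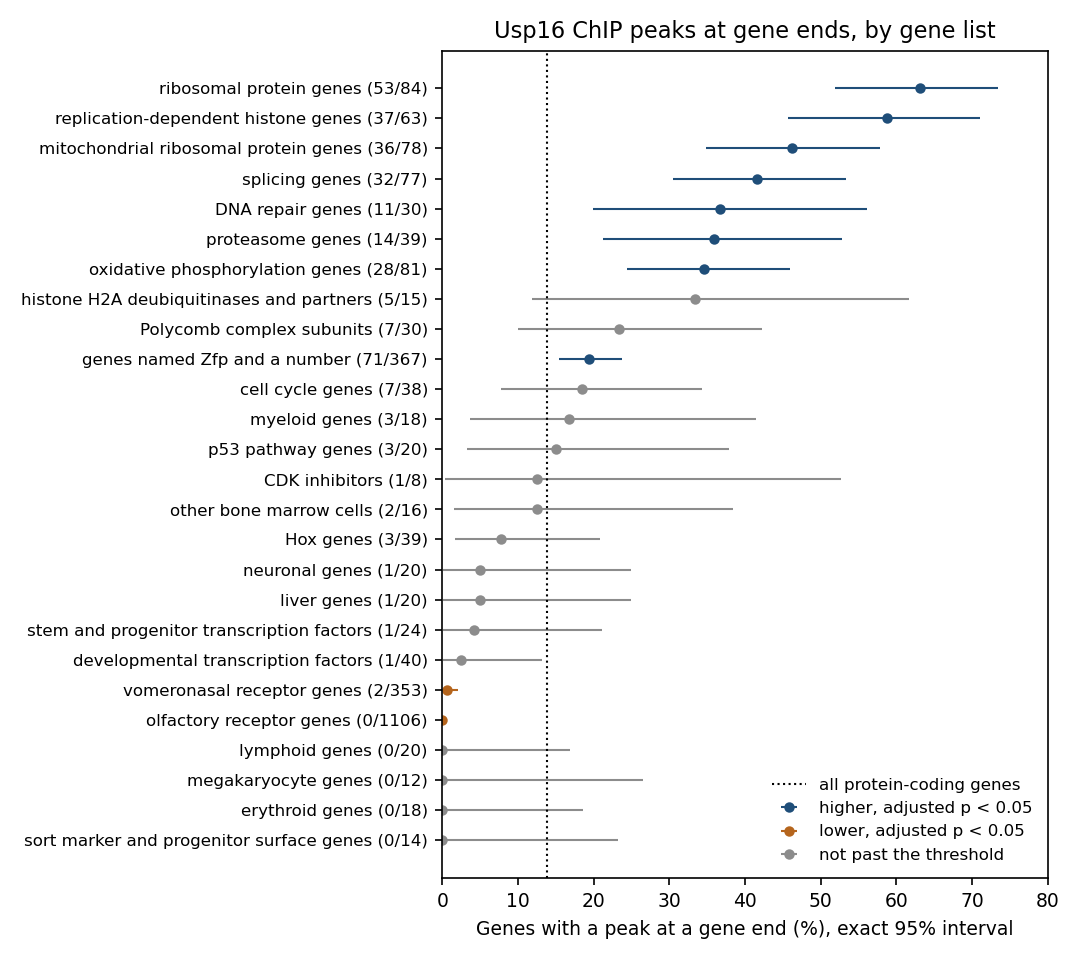
Percent of the genes of each fixed list that carried a Usp16 ChIP peak at a gene end (points) with exact 95% intervals (lines) and the numbers of genes in brackets, blue for lists past the threshold above other genes, brown for those below and grey for the rest. The dotted line marks the 13.9% of all protein-coding genes, and ribosomal protein genes reach 63.1%.

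Chemosensory receptor genes carried peaks less often. None of 1106 olfactory receptor genes, such as Olfr1 and Olfr10, carried one (upper 95% bound of the odds ratio 0.02, adjusted exact p = 1.3e-72). Of 353 vomeronasal receptor genes only Vmn2r29 and Vmn2r4 (score 130) did (0.57%, odds ratio 0.03, interval 0.0042 to 0.13, adjusted exact p = 2.4e-19), and Vmn1r1 and Vmn1r10 did not. The odds ratio of the vomeronasal list was 0.019 with a window of 500 bp, 0.064 with the 2524 highest-scoring peaks and 0.074 within the strata. Mappability of these receptor genes was not tested, so the low counts do not show absent binding.

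The lists of genes that mark blood stem cells and their progeny did not pass the threshold. Of 24 stem and progenitor transcription factor genes only Nkap carried a peak (score 113, odds ratio 0.27, interval 0.0066 to 1.66, adjusted exact p = 0.37, and odds ratio 0.50 with the 2524 highest-scoring peaks), and Cbfb and Erg did not. None was listed at the ends of the 14 sort marker and progenitor surface genes (among them Cd27 and Cd34), the 18 erythroid genes (Alas2, Ank1), the 20 lymphoid genes (Bcl11b, Blnk) or the 12 megakaryocyte genes (Gp1ba, Gp1bb), with adjusted exact p of 0.37, 0.30, 0.20 and 0.49. The upper 95% bounds of their odds ratios were 1.87, 1.41, 1.26 and 2.24, so a share like that of other genes was not excluded for any of these 4 lists. Ank1 held 1 peak inside the gene, 54.8 kb from its nearer end. Of 18 myeloid genes 3 carried a peak (odds ratio 1.24, adjusted exact p = 0.81), with Cebpa, a myeloid transcription factor gene, at 92.5, Cd68, whose peak also reached Mpdu1, at 55.9 and Fcgr3 at 54.9. The Fcgr3 peak also covered ends of tRNA genes such as n-TEctc5. The odds ratio of this list was 0.67 with the 2524 highest-scoring peaks, 0.83 with overlap by at least 50% of the peak, 0.80 without the peaks at tRNA, snRNA or snoRNA gene ends and 2.07 within the strata, so it had no stable direction. Camp and Cebpe carried none. Of 16 genes of stroma and endothelium 2 carried a peak, Col1a1 (60.1) and Pdgfra (57.1), and Acta2 and Adipoq did not (odds ratio 0.89, adjusted exact p = 1, and odds ratio 1.07 within the strata).

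The lists on cell division, the p53 pathway and chromatin regulators did not pass either, by the same Fisher's exact test. Of 8 CDK inhibitor genes Cdkn2d alone carried a peak, of score 50.1, close to the lowest score listed, and Cdkn1b had none (odds ratio 0.89, adjusted exact p = 1). The odds ratio was 0 with the 2524 highest-scoring peaks, 1.49 with a window of 5 kb and 1.42 within the strata, so it had no stable direction. Of 38 cell cycle genes 7 did (odds ratio 1.40, interval 0.52 to 3.26, adjusted exact p = 0.56), led by Mcm4 (159, the peak also counted for Prkdc), Aurka (82.3), Cdk4 (77.4) and Mcm7 (72.2), while Aurkb and Bub1 did not. Of 20 p53 pathway genes 3 did, Sesn2 (61.1), Mdm2 (57.2) and Trp53 (53.5), and Aen and Bax did not (odds ratio 1.10, adjusted exact p = 0.81, and odds ratio 0 with the 2524 highest-scoring peaks). Of 30 Polycomb subunit genes 7 did (odds ratio 1.89, interval 0.69 to 4.56, adjusted exact p = 0.31). They were led by Jarid2 (123), Eed (91.4), Pcgf2 (83.4) and Mtf2 (73.1), and Aebp2 and Bmi1 had none. Of 15 genes for H2A deubiquitinases and their partners 5 did (33.3%, odds ratio 3.11, interval 0.83 to 9.999, unadjusted p = 0.046, adjusted exact p = 0.0996). These were Usp21 (168), Usp3 (125), Asxl1 (91.2) and Usp12 (77.7), and Mysm1, which is named after its value was seen. Asxl2 and Bap1 had none.

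Lists of genes of other tissues and of development also had few carriers, and none of these 4 lists passed Fisher's exact test. Of 40 developmental transcription factor genes Tbx3 alone carried a peak (score 61.1, odds ratio 0.16, interval 0.0039 to 0.94, unadjusted p = 0.036, adjusted exact p = 0.086), and Barx1 had none. This list passed with a window of 5 kb, at an odds ratio of 0.11 (adjusted exact p = 0.016), while under the other settings its adjusted p lay between 0.086 and 0.31. Of 20 liver genes Apoa2 carried one (111, shared with Tomm40l), unlike Ahsg and Alb, and of 20 neuronal genes Snap25 did (85.5), unlike Camk2a and Cntnap2 (odds ratio 0.33 and adjusted exact p = 0.46 for each list). Of 39 Hox genes Hoxc5 (73.8), Hoxc10 (71.6) and Hoxa9 (52.6) did, and Hoxa10 did not (odds ratio 0.52, interval 0.10 to 1.64, adjusted exact p = 0.46). With a window of 5 kb the odds ratio of the Hox list was 0.98, close to that of other genes.

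Some of the highest-scoring peaks lay far from gene ends. Of the 10 highest-scoring peaks 4 were farther than 10 kb from any annotated gene end, against 14 of the highest 50 (28%), 94 of the highest 500 (18.8%) and 1271 of all 5046 (25.2%), and these shares were not tested. The highest score in the list, 2409, was at chromosome X 170757968 to 170758575, a stretch of 608 bp between genes, 80.2 kb from the nearest protein-coding gene, Asmt. The next such peaks lay inside Clnk (score 725, chromosome 5, 38736494 to 38737184), inside Lama1 (688, chromosome 17, 67741093 to 67741747) and inside Flt1 (645, chromosome 5, 147611326 to 147611707). The last of the 5 lay on chromosome Y between genes (644, 4036424 to 4036989), with Gm3376 nearest at 253 kb. Mappability was not tested and the IgG signal was not analysed here, so these scores cannot be read as the strongest Usp16 binding.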

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

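The count of peaks at tRNA genes was made, and its tests were chosen, after the list had been looked through, while the outcome each test would need was set before its own value was seen, except for the counts of genes alone in their family. Genes for small RNAs were outside the comparisons of protein-coding genes, and tRNA genes stood out there: 151 of 408 carried a gene-end peak (37.0%, exact 95% interval 32.3 to 41.9%), against 13.9% of protein-coding genes and 0.43% of pseudogenes. Spillover from neighbouring protein-coding genes as the whole cause was argued against. Of the 300 tRNA genes farther than 5 kb from any protein-coding gene end, 72 still carried a peak (24.0%, interval 19.3 to 29.2%). This share was below the 37.0% of all 408 tRNA genes, so a part played by such neighbours was not excluded. Several tRNA genes sharing 1 peak was argued against too, since 32.6% of 270 loci, made by joining tRNA genes within 2 kb, held a peak (27.0 to 38.5%). Reads shared between gene copies remain open: the share was 52.3% in anticodon families of 5 or fewer annotated copies (34 of 65, interval 39.5 to 64.9%), but that test was ill chosen, since all 34 lay in families of 3 to 5 copies, which can still share reads, and none of the 10 genes alone in their family carried a peak (0 to 30.8%), nor any of the 4 left alone when different spellings of an anticodon are joined (0 to 60.2%). General recovery of open, heavily transcribed chromatin in any precipitation is open too because the IgG signal was not analysed here, and no biological explanation was tested.

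Contigs outside the assembled chromosomes, which the comparisons with genes leave out, held 33 peaks with a median score of 108 and a median width of 1294 bp, against 69.9 and 683 bp on the assembled chromosomes. Mappability was not tested and the IgG signal was not analysed here, so the cause of this difference is open. The highest of them scored 643, on the contig GL456383.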

How the results depend on the processing

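The strata, the local shift, the removal of peaks at small RNA genes, the counting of shared peaks once, the classes among peaks away from gene ends and the widths were chosen after seeing the data. Of 235 recomputed values 219 stayed within 1.5 times for counts or kept their side of the threshold, with the same direction where they had passed it. Protein-coding genes with a gene-end peak numbered 1757 with the 2524 highest-scoring peaks, in place of 3033, by construction since fewer peaks entered. They numbered from 2836 to 4009 under the other windows and overlap rules. The same peaks took 2 lists below the threshold, DNA repair genes at an odds ratio of 2.87 and Zfp genes at 1.17, and the cause was not tested. The list of developmental transcription factors passed with a window of 5 kb, at an odds ratio of 0.11, and the cause was not tested. Between 8 and 11 lists passed over all settings. Of lists that did not pass, the odds ratio crossed 1 for myeloid genes (0.67, 0.83 and 0.80), p53 pathway genes (0 with the 2524 highest-scoring peaks), CDK inhibitors (1.49 at 5 kb and 1.42 in strata, against 0 with the 2524 highest-scoring peaks) and stroma and endothelium (1.07 in strata). Of the genes named by the rule, the peak given did not count at Fosb, Rpl22 and Apoa2 with a window of 500 bp or overlap by at least 50% of the peak, at Snap25 and Vmn2r4 with the 500 bp window, and at Cd68 with the 50% overlap. Among peaks away from gene ends the shares inside protein-coding genes (46.2%) and inside other genes (8.99%) lay above random in place of below. Among all peaks these 2 shares were lower by construction, since the peaks at gene ends take up part of the whole. Against the share of protein-coding genes in place of length, the ratio of observed to expected peaks turned on several chromosomes. Of those past the threshold against length, these were 7 (0.76), 9 (0.98), 11 (0.92), 12 (1.20), 17 (0.99) and 19 (0.92). This follows from the scaling, since their gene density differs from the genome's. Other chromosomes turned too, such as 1 (0.98 to 1.29), 3 (0.91 to 1.20) and 18 (0.95 to 1.32). No paired analysis was possible because each antibody had 1 library. Strata of promoter CpG content, sequence motifs and the most upstream start were not run, since no sequence or strand was used. Unknown read depth and the lowest listed score of 50 limit every statement about genes without a peak.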

Other observations

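The counts at small RNA genes, the comparison of the 50 highest-scoring peaks, the pooled test of blood cell genes and the strata of gene length were chosen only after the list had been seen. Several genes for small structural RNAs other than tRNA had high-scoring peaks. A gene annotated as snRNA had an end at 12 of the 50 highest-scoring peaks (24.0%, exact 95% interval 13.1 to 38.2%) and at 48 of the other 4996 (0.96%, interval 0.71 to 1.27%), a description of the peaks that prompted it and not a test. Examples, picked by their scores, are the U3 genes Rnu3b2 (657), Rnu3b3 (598), Rnu3b4 (529) and Rnu3b1 (496), which lie between 87443237 and 87471582 on chromosome 11, are similar copies and make up 4 of the 12 peaks, and Rnu11 (544), the gene for the U11 RNA of the minor spliceosome. The 2 annotated Y RNA genes Rny3 and Rny1 had peaks of score 450.2 and 335. Rmrp, the RNA of RNase MRP, had a peak of score 351, Rpph1, the RNA of RNase P, one of 243, and the 7S RNA genes Rn7s2 and Rn7s1 ones of 133 and 113. Rmrp, Rpph1 and Rn7s1 lie 0.281, 0.126 and 0.109 kb from a protein-coding gene end, so their peaks cannot be assigned to 1 gene. Rny3, Rny1 and Rn7s2 lie 14.4, 7.96 and 3.98 kb from one. No peak was listed at the ends of the 63 annotated rRNA genes. The exact 95% interval of this share, 0 to 5.69%, includes the 4.13% of all lncRNA genes.

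Among the 408 tRNA genes the highest scores were at n-TFgaa3 and n-TNgtt7 (290), beside Ndufs7, and at n-TEctc10 and n-TLcaa3 (188), 4.81 and 4.48 kb from the nearest protein-coding gene end. All 6 genes of the family n-TRacg carried a peak, and 2 of the 56 of n-TCgca did. Of genes more than 5 kb from any protein-coding gene end, 4.58% of 851 snRNA genes, 0.28% of 1064 snoRNA genes, 0.87% of 809 miRNA genes and 1.67% of 8882 lncRNA genes carried a peak.

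One hypothesis was that genes of blood cells, pooled over their lists, carry gene-end peaks as often as other genes. Pooled, the 6 lists held 4 genes with a peak among 106 (3.77%), namely Nkap, Cebpa, Cd68 and Fcgr3, and the odds ratio was 0.24 (interval 0.065 to 0.64, two-sided Fisher's exact p = 0.0010). Within strata of gene length and neighbouring gene ends it was 0.27 (0.10 to 0.76). The lists were pooled after their counts had been seen, so these values restate that pattern and the hypothesis stays open. A list of called peaks does not separate genes without the protein from genes whose signal fell below the lowest score. Low shares were not limited to blood cell genes. They were 2.5% of 40 developmental transcription factor genes, 5% each of 20 liver and 20 neuronal genes and 7.69% of 39 Hox genes. Genes of stroma and endothelium stood at 12.5% of 16. The pooled blood cell lists were not tested against these lists.

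Chromosome X had fewer peaks per Mb than any autosome. Low gene content as the whole cause was argued against, since peaks farther than 10 kb from any annotated gene end were also sparse on X, at 0.211 per Mb (Poisson interval 0.148 to 0.292) against 0.365 on the lowest autosome, chromosome 7. Male cells with a single X could give fewer listed peaks, and this cannot be told apart from other causes, because the sex of the mice is not in the labels and the peaks on Y do not decide it: 7 were listed there, 1 of them with a score of 644, but 0 of 256 protein-coding genes on Y carried a gene-end peak. Of 966 protein-coding genes on X 3.73% carried one (interval 2.62 to 5.12%), against 14.5% of 20665 on autosomes. Mappability and assembly gaps were not tested, and no biological explanation was tested.

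Gene length and neighbouring gene ends could raise the chance of a peak near an end, and so the counts of the 8 lists with more peaks. Genes were compared within 12 strata of length and of other protein-coding gene ends within 2 kb. All 8 lists stayed past the threshold, and the lowest lower bound of their odds ratios was 1.16, for DNA repair genes. This argues against length and crowding by protein-coding gene ends as the whole cause. Ends of other kinds of genes did not enter the strata, so crowding by them was not adjusted for. The odds ratio was lower within the strata for 6 of the 8 lists, such as histone genes (8.94 to 4.51), and higher for ribosomal protein genes (10.8 to 11.4) and Zfp genes (1.5 to 1.60). Transcription level, promoter CpG content and a general recovery of open chromatin stay open, since none was measured here, and no biological explanation was tested.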
